A study of Mus musculus with 8 samples.

How the data were processed

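Total RNA from the hippocampus of 3-week-old mice, 4 WT and 4 AS animals, was measured on 1-colour Agilent expression arrays, 1 array per animal. Per the labels' protocols, RNA was extracted with TRIzol, purified on columns with DNase treatment and labelled with Cy3 by T7 amplification. The labels number the animals as biological replicates 1 to 4 of each group. Per the file headers, the spots were read with Agilent Feature Extraction 9.5.1.1, and the submitters' processing notes name Feature Extraction 9.5 and limma 3.30.13. The deposited intensity of each spot used here is the processed signal, which per the file headers was background-subtracted and detrended within the array and not scaled between arrays. The deposited mean spot intensity and median local background were used in an alternative.

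The deposited log2 table of the whole series does not state its scale, centring or direction. It was recomputed from the scanner intensities by normexp background correction with an offset of 16, quantile normalization and log2, averaged by probe. All 39485 entries were matched with differences of at most 5e-09, which settled the log2 scale and left no unknown centring or direction. The column medians were 6.98, 6.97, 6.98 and 6.98 for WT replicates 1 to 4 and 6.98, 6.97, 6.98 and 6.98 for AS replicates 1 to 4. This table served as an alternative only.

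Each array held 44397 spots, of which 43020 were not controls. The value used was log2 of the processed signal minus the array's 75th percentile of it over spots that are not controls. Spots with an outlier flag were left out and spots of 1 probe were averaged, giving 39429 probes. A probe was tested if it was well above background on at least 4 of the 8 arrays (26014 probes), and a gene was represented by its brightest probe (20014 genes). Probes were named by matching unversioned accessions to a RefSeq gene table, used for names only. In all, 26761 probes matched, 2878 symbols were updated, and other probes kept the name in the file. Positions are those of the array design (mm9). For arrays, their number limits the precision: the median residual SD was 0.139 on the log2 scale.

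Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment over genes and a threshold of adjusted p 0.05. The model, the alternatives, the 40 gene lists and the rule for naming genes were fixed before the data were examined. Lists of at least 5 tested genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, and each list was also adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

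The naming rule took every Ube3a probe and every detected region gene, then up to 12 genes per direction past the threshold with no overlap between groups, filled up by the smallest p among genes above background on all 8 arrays. From each list described it took the members past the threshold over the list alone or, with none, up to 4 with the smallest p. Of the region genes, 1 is counted in the totals and not reported here by itself. Features with Riken, predicted or accession names were not named by this rule. What counts as a gene symbol was widened after values had been seen, to take in older symbols as the rule's wording asks, and this added Hist1h4i to the named genes.

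The arrays lay on 2 slides, each with 2 WT and 2 AS arrays, and scan followed slide exactly. Slide was therefore tested as a block and within each slide. On both slides the AS arrays lay at positions 1 and 3 and the WT arrays at positions 2 and 4. Group therefore cannot be told apart from array position, and no alternative covers it. Other alternatives were the scaling, the background correction, the filter on dim probes, outlier flags, the treatment of several probes per gene, the variance model, array weights, the replicate number as a block, thresholds, and leaving out each array. Sex as a covariate, the choroid plexus score as a covariate and arrays from females alone were added after the data had been seen. The sex of each animal was read from Xist and Y-linked transcripts, since the labels do not give it.

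The comparison was tested on simulated data for 20014 genes with the real arrays' means and spread, 4 against 4, in which 200 genes were changed, 50 at each size. Of those changed 1.25-fold 18% were recovered, of those changed 1.5-fold 60%, of those changed 2-fold 84%, and of those changed 3-fold 92%, with 7 false calls. These shares hold for 200 changed genes drawn independently of each other. The adjustment is stricter where fewer genes pass, and 3 features passed in the real data. The shares therefore do not give the recovery in the real comparison, which could be lower.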

Results

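Gene expression was measured in the hippocampus of 3-week-old mice, comparing a model of Angelman syndrome (AS) with wild-type (WT) animals on the C57BL/6 background. Angelman syndrome is a neurodevelopmental disorder caused by loss of the maternal copy of Ube3a, which encodes an E3 ubiquitin ligase and is expressed mainly from the maternal allele in neurons. The labels describe 4 biological replicates per group, each hybridised to its own single-colour Agilent array, so 8 arrays entered every comparison. The submitters also describe the animals as 4 pairs without saying what pairs them. The main comparison did not pair the animals. Between 62.7% and 70.4% of the 39429 distinct probes were well above background on each array, and the 75th percentile of the processed signal lay between 1223 and 1707. Correlations between arrays ran from 0.990 to 0.997, and no pair of arrays held identical values. Xist and the Y-linked transcripts Ddx3y and Eif2s3y separated 3 female and 1 male WT animals from 2 female and 2 male AS animals. The number of arrays limits the precision of every value. Group also followed array position on the slides, so a difference between groups cannot be told apart from one between positions.

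Ube3a, the gene whose loss defines the model, was examined first. Its probe at chromosome 7, 66561271 to 66561330 (mm9), with the sequence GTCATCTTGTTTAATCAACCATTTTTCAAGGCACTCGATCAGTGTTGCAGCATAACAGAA, was well above background on all 8 arrays. It averaged -1.64 ± 0.09 (SD, n = 4) in AS and -1.47 ± 0.15 (SD, n = 4) in WT hippocampus, in log2 units relative to each array's 75th percentile. The log2 difference was -0.17, with a 95% confidence interval from -0.38 to 0.03, and it was not past the threshold (limma adjusted p = 0.413). An exact two-sided permutation test of the same values gave p = 0.114, where the smallest p that 4 against 4 allows is 0.0286. The difference was -0.26 on the first slide and -0.09 on the other, and the adjusted p was 0.34 with slide as a block. With the choroid plexus score as a covariate, an alternative chosen after the data were seen, the difference was -0.09. A further Ube3a probe at 66544981 to 66545040 was well above background on only 2 of the 8 arrays and differed by -0.24 with a standard error of 0.41. The labels give neither the allele nor the exon that was changed, so these probes do not check the genotype of any array.

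Genes around Ube3a, several of them imprinted, were compared next because the labels do not give the size of the deleted part. Of the 17 region genes tested, 13 had higher and 4 had lower means in AS, and 0 passed adjusted p 0.05 either adjusted over the list alone or over all genes (limma; 0 also at an unadjusted p under 0.05). The paternally expressed Snrpn and Ndn differed by 0.12 and 0.25 on the log2 scale, and Magel2, Peg12, Mkrn3 and Ipw by 0.18, 0.19, 0.10 and 0.15. The GABA-A receptor subunit genes Gabra5 and Gabrg3 differed by -0.07 and 0.27. Cyfip1, Nipa1, Nipa2 and Tubgcp5 differed by 0.08, 0.01, 0.10 and 0.17, Herc2 by -0.11, Atp10a by 0.15 and the pigmentation gene Oca2 by -0.60. Further probes gave other sizes for some of these genes: another Snrpn probe at 67127426 to 67127485 differed by 0.43 with a standard error of 0.08, and another Gabrg3 probe at 63979783 to 63979842 by 1.16 with a standard error of 0.31. With every probe tested by itself, 1 probe of the region passed, adjusted over the list alone. The small value of Nipa1 turned negative under quantile normalization. Ipw differed by 0.73 on the first slide and -0.43 on the other, and Magel2 by -0.16 and 0.52; without AS replicate 1 the Ipw difference was -0.21, and without WT replicate 4 the Magel2 difference was -0.03.

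**Figure D1:**
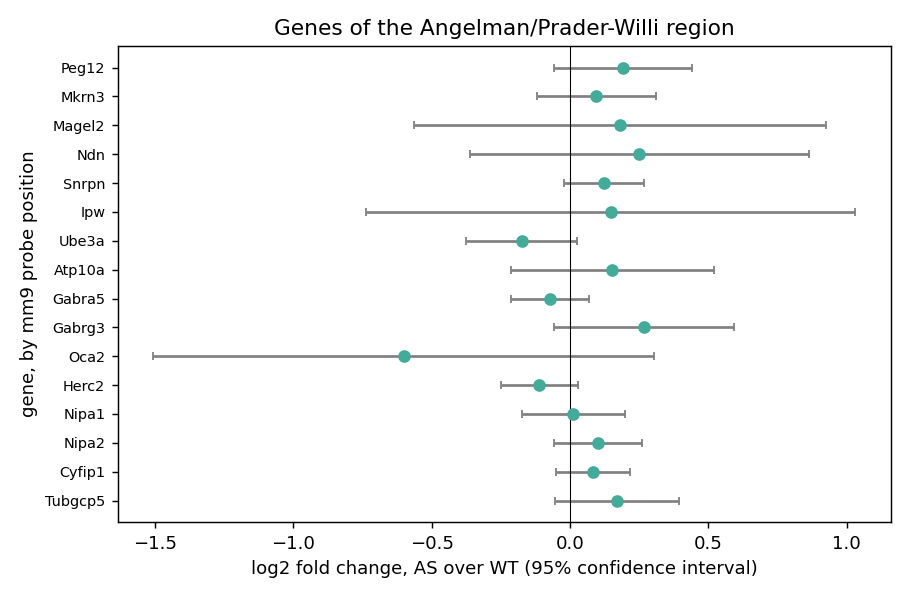
Log2 fold change of AS over WT for the region genes named in the text, in the order of their probe positions on chromosome 7; points are limma estimates and bars their 95% confidence intervals (4 arrays per group). None of the genes shown passed adjusted p 0.05, and the Ube3a point lies at -0.17.

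Across the 20014 genes tested, 3 features differed between AS and WT at adjusted p 0.05, of which 2 were higher and 1 was lower in AS. Hddc3, which encodes an HD domain hydrolase, rose 2.94-fold, a log2 difference of 1.56 with a standard error of 0.11 (adjusted p = 0.00764). Its values were -1.17 ± 0.12 in AS and -2.72 ± 0.20 in WT (SD, n = 4 each), measured by a probe at chromosome 7, 87488629 to 87488688 (mm9). The other features carry no gene symbol of the kind the naming rule allows and were named after their values were seen. The Riken transcript 1500012K07Rik at chromosome 7, 82463310 to 82463369, fell to 0.544 of its WT level, a log2 difference of -0.88 with a standard error of 0.07 (adjusted p = 0.00764). The transcript ENSMUST00000101255 at chromosome 11, 50905258 to 50905317, rose 1.79-fold, a log2 difference of 0.84 with a standard error of 0.08 (adjusted p = 0.037). Both had low signals, though well above background on every array, and their fold changes depended on the background correction. The means in AS and WT were -4.97 and -4.09 for 1500012K07Rik, and -3.58 and -4.42 for ENSMUST00000101255. The differences on the 2 slides were 1.36 and 1.75 for Hddc3, -0.77 and -0.99 for 1500012K07Rik, and 0.91 and 0.78 for ENSMUST00000101255. A shared sign follows from choosing by p, since 99.9% of the genes at an unadjusted p under 0.05 (limma) had it. Across genes, the differences on the 2 slides correlated at only 0.135. In each of the 3 features the 4 AS values lay on one side of the 4 WT values. That separation also largely follows from choosing by p and is no separate evidence. The files give no exon, intron or UTR for these probes, and no other tested probe of the same feature stands beside any of them.

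**Figure D2:**
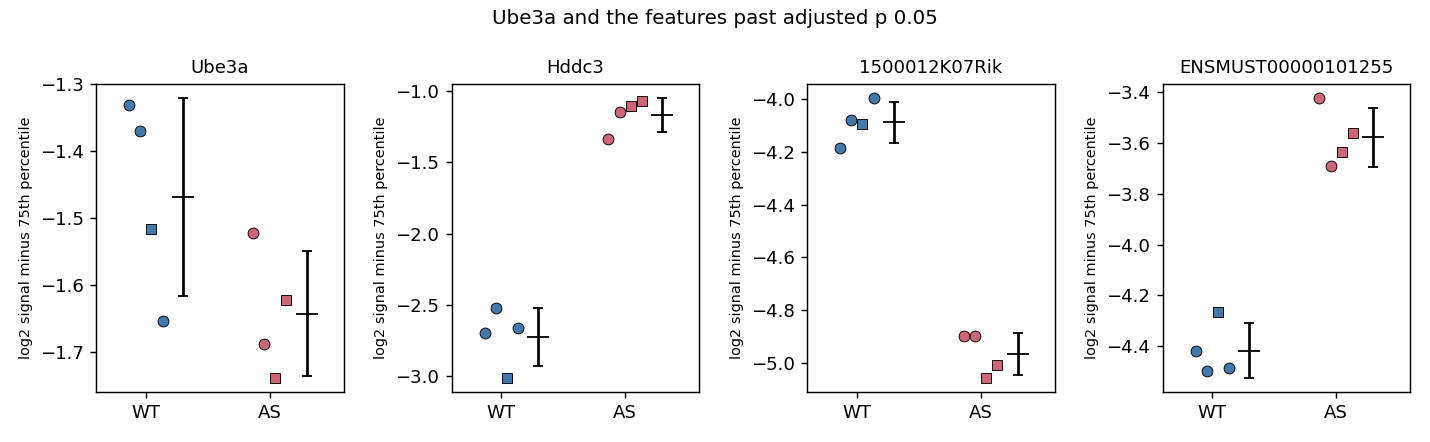
Log2 signal relative to each array's 75th percentile for Ube3a and for the features past adjusted p 0.05; circles are arrays from females, squares arrays from males, and bars show the group mean and SD (n = 4). The WT and AS points do not overlap for Hddc3, 1500012K07Rik and ENSMUST00000101255, which were chosen by p, whereas they overlap for Ube3a.

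At an unadjusted p under 0.05, 2787 genes differed, 1708 higher and 1079 lower in AS, where chance alone gives 1001. Quantile normalization gave 1367 higher and 1400 lower, and normexp background correction with the 75th percentile gave 1204 higher and 1722 lower, so the balance of directions depended on the scaling and the background correction. The groups did not overlap for 1920 genes, or 9.59%, where chance gives 2.86%. With slide as a block 2 features passed adjusted p 0.05, ENSMUST00000101255 no longer among them (adjusted p = 0.0837), and within each slide, at 2 arrays per group, 0 passed, with 1739 and 1544 genes at an unadjusted p under 0.05 by limma. Of the left-out arrays, omitting AS replicate 1 gave 15 features and omitting WT replicate 2 gave 1; 1500012K07Rik missed the threshold without WT replicate 2 (adjusted p = 0.0646) or AS replicate 4 (adjusted p = 0.0502), and of the 8 omissions ENSMUST00000101255 passed only in those of WT replicate 3 and AS replicate 1. Hddc3 passed in 22 of 25 alternatives. The replicate number as a block is the fit that would match the described pairs, if these follow the numbers. With that block 0 features passed (limma, 3736 at an unadjusted p under 0.05), and Hddc3 missed the threshold (log2 difference 1.56, adjusted p = 0.0812). Hddc3 also missed it with the choroid plexus score as a covariate (log2 difference 1.52, adjusted p = 0.0698) and in arrays from females alone (1.38, adjusted p = 0.304). Normexp correction with the 75th percentile gave -0.49 for 1500012K07Rik and 0.40 for ENSMUST00000101255.

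Genes with symbols that came next in rank did not pass and are given as values. Among those with higher means in AS, the largest log2 differences were 1.46 for Plac8, a gene of myeloid and lymphoid cells, and 1.00 for Nphs1, which encodes nephrin, followed by 0.81 for the cold-inducible RNA-binding protein gene Rbm3 and 0.81 for R3hdml. Plac8 and R3hdml had low signals, averaging -5.96 and -5.87 in WT and -4.50 and -5.06 in AS. Another tested probe of Plac8, like another of Siglecf, had the same sign but no unadjusted p under 0.05 (limma). Camk2n2, which encodes an inhibitor of the calcium/calmodulin-dependent kinase CaMKII, differed by 0.49 with a standard error of 0.07, and the histone methyltransferase gene Suv39h1 by 0.49. Spata21, Siglecf, S100a4, Deaf1 and Cage1 differed by 0.63, 0.54, 0.52, 0.48 and 0.44, and the adjusted p-values of all 11 ran from 0.0541 to 0.0959. Among those with lower means, 4 were histone genes: H2bc6 at -1.11, H3c15 at -0.87, Hist1h4i at -0.74 and H2bc1 at -0.49; histone genes have near-identical copies, which makes these probe values uncertain. Apln, the gene of the peptide ligand apelin, differed by -0.73 with a standard error of 0.09, and Rab38, which encodes a small GTPase, by -0.79. Dnd1, Dpp7, Wfs1, Lynx1, Scly and Acaa1b differed by -0.55, -0.51, -0.49, -0.46, -0.41 and -0.40, and the adjusted p-values of all 12 ran from 0.0832 to 0.112. On the first and the other slide Plac8 differed by 1.26 and 1.66, Camk2n2 by 0.54 and 0.45, and Apln by -0.68 and -0.78. These genes were chosen by a small p over both slides, so the shared signs are no separate evidence. Wfs1 encodes the endoplasmic reticulum protein wolframin and Lynx1 a modulator of nicotinic acetylcholine receptors.

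Interferon-stimulated genes, which respond to antiviral cytokine signalling, rose as a group: 29 of the 30 tested had higher means in AS, with a median log2 difference of 0.43 (camera adjusted p = 1.92e-08). That call was lost with an estimated correlation between genes (adjusted p = 0.746). Adjusted over the list alone, 4 members passed, and 0 passed over all genes tested (limma; 16 at an unadjusted p under 0.05). Those past over the list alone were the antiviral enzyme genes Rsad2 and Oas1a, at log2 differences of 1.01 and 0.83, Trim30a at 0.65 and the immunoproteasome subunit gene Psmb8 at 0.38. The score of the list, its members' mean deviation on each array, was 0.38, 0.51 and 0.43 on AS replicates 2, 3 and 4, and -0.31 on AS replicate 1, inside the WT range of -0.36 to -0.16. Without AS replicate 1 the median was 0.58, with normexp correction and the 75th percentile it was 0.25, and in arrays from females alone it was also 0.25. The group difference in the score was 0.30 on the first slide and 0.71 on the other.

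Cell cycle genes had lower means in AS for 23 of 29, with a median log2 difference of -0.19. Camera gave adjusted p = 2.75e-06 at the preset correlation and adjusted p = 0.746 with an estimated correlation. Adjusted over the list alone 3 members passed, all mitotic: the ubiquitin-conjugating enzyme gene Ube2c at -0.53, the spindle midzone gene Prc1 at -0.47 and the kinesin gene Kif20a at -0.42. The Prc1 probe lies at chromosome 7, 87461048 to 87461107 (mm9). The probe of the called feature Hddc3, which was higher in AS, lies close by at 87488629 to 87488688. For Prc1 a change with the list and a local one on chromosome 7 cannot be told apart. Heat shock and unfolded protein response genes had lower means in AS for 21 of 23, with a median of -0.17. Camera gave adjusted p = 0.000411 at the preset correlation and adjusted p = 0.746 with an estimated correlation. Adjusted over the list alone, 0 members passed (limma, 2 at an unadjusted p under 0.05). The chaperone genes Hsph1, Hspa1a and Calr differed by -0.40, -0.33 and -0.27, and the stress-induced transcription factor gene Ddit3 by -0.16. The median of the heat shock list was -0.09 without WT replicate 1 and also -0.09 with the choroid plexus covariate, and that of the cell cycle list was -0.10 under normexp correction with quantile normalization. The scores of the cell cycle list differed by -0.20 and -0.15 and those of the heat shock list by -0.18 and -0.17 on the 2 slides.

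Markers of choroid plexus, the tissue that secretes cerebrospinal fluid and lies against the hippocampus, were lower in AS for 26 of 26 genes, with a median log2 difference of -1.32 (camera adjusted p = 1.92e-08; adjusted p = 0.746 with an estimated correlation). Adjusted over the list alone 0 members passed (limma; 3 at an unadjusted p under 0.05), and Cdr2, Igfbp2, Ace and Sostdc1 differed by -1.03, -0.89, -0.77 and -1.24. The spread between arrays of one group was large: the list score was 2.52, 0.67, 1.15 and -1.67 on WT replicates 1 to 4 and -0.15, -1.83, -0.07 and -0.62 on AS replicates 1 to 4. The score differed by -2.59 on the first slide and by -0.09 on the other, and the median was -0.70 without WT replicate 1 and -2.13 without WT replicate 4. Ependymal and cilia markers had lower means in AS for 16 of 18 genes, with a median of -0.48. For them camera gave adjusted p = 3.02e-05 at the preset correlation and adjusted p = 0.746 with an estimated correlation. The ciliary dynein gene Dnah5 at -0.37 and the phospholipid transfer protein gene Pltp at -0.33 passed adjusted over the list alone. Their score differed by -0.85 on the first slide and 0.07 on the other, so the direction was not shared between the slides, and the median was -0.30 without AS replicate 1, -0.26 with the choroid plexus covariate and -0.83 in females.

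Oligodendrocyte and myelin markers were lower in AS for 24 of 28 genes, with a median of -0.15 (camera adjusted p = 0.00148; adjusted p = 0.853 with an estimated correlation). Ugt8a, Trf and Ermn differed by -0.47, -0.41 and -0.48 and Itpr2 by 0.14, while 0 members passed adjusted over the list alone (limma; 3 at an unadjusted p under 0.05). Another Ermn probe gave 0.25. The median was -0.06 without AS replicate 1 (adjusted p = 0.494) and -0.11 without WT replicate 2 (adjusted p = 0.0621), but -0.26 without AS replicate 3 (adjusted p = 1.54e-07) and -0.40 in arrays from females alone. The score differed by -0.44 on the first slide and 0.12 on the other. Blood cell markers were higher for 12 of 14 genes with a median of 0.35 (camera adjusted p = 0.036; adjusted p = 0.746 with an estimated correlation), and Plac8 was the 1 member past the threshold adjusted over the list alone. The Plac8 probe had a low signal, and another tested Plac8 probe had no unadjusted p under 0.05 (limma). The blood score differed by 0.58 and 0.25 on the 2 slides, and the call was lost without WT replicate 2, 3 or 4 or AS replicate 1 (adjusted p = 0.123, 0.0942, 0.0606 and 0.134), with medians of 0.34, 0.28, 0.31 and 0.20, and in arrays from females alone (0.40, adjusted p = 0.0581). With slide as a block, which cannot move a median because each slide holds 2 arrays of each group, the 7 camera calls had adjusted p-values from 1.36e-08 to 0.0459. Of the members of all 40 lists, 0 passed over all genes tested (limma).

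**Figure D3:**
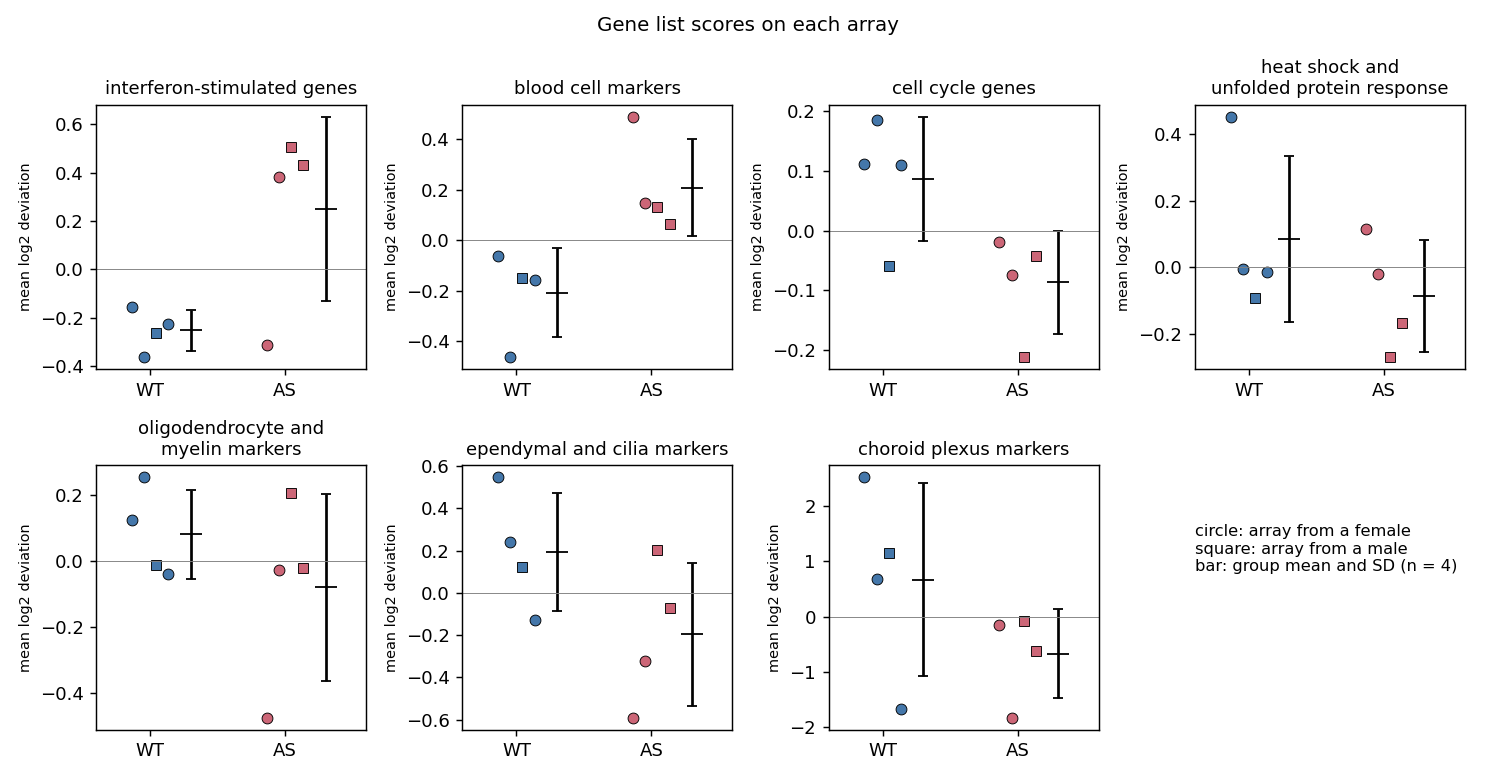
Mean log2 deviation of each list's tested members on every array, for the 7 lists past camera adjusted p 0.05; circles are arrays from females, squares arrays from males, and bars show the group mean and SD (n = 4). The interferon score of AS replicate 1 (-0.31) lies among the WT arrays, and the choroid plexus score spans -1.67 to 2.52 within the WT group.

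The other 32 lists tested with camera were not past adjusted p 0.05. Closest were proteasome subunits (35 of 44 higher, median 0.06, adjusted p = 0.0601), retinoic acid signalling (11 of 19 lower, adjusted p = 0.12), microglia markers (14 of 21 higher, adjusted p = 0.154) and GABA receptors and transport (16 of 22 higher, adjusted p = 0.2). Reported UBE3A substrates and partners had a median of 0.03 over 26 genes (adjusted p = 0.947), the region list 0.10 (adjusted p = 0.599) and other imprinted genes 0.05 (adjusted p = 0.38). For the neuronal lists the adjusted p was 0.38 for glutamate receptors and postsynaptic density, 0.341 for axon initial segment and sodium pump, 0.997 for potassium and calcium channels, 0.886 for monoamine and neuromodulator receptors, 0.788 for immediate early genes, 0.63 for interneuron markers and 0.416 for immature neuron and neurogenesis markers. It was 0.768 for dentate granule cell, 0.651 for CA1 pyramidal and 0.341 for CA2 and CA3 pyramidal markers, 0.375 for cortex, 0.997 for thalamus, 0.347 for striatum and amygdala and 0.63 for hypothalamus and other neuropeptides. It was 0.713 for oligodendrocyte precursor, 0.406 for astrocyte, 0.566 for endothelial and mural and 0.341 for meningeal and fibroblast markers. It was 0.38 for glucocorticoid-responsive genes, 0.635 for the mTOR pathway, 0.997 for the circadian clock, 0.646 for oxidative phosphorylation, 0.713 for cytosolic ribosomal proteins, 0.532 for BMP and TGF-beta signalling and 0.475 for extracellular matrix and perineuronal net. Only 1 sex-linked transcript was tested, too few for a list test. Median, mean and camera direction differed in sign for immediate early genes, the mTOR pathway, the circadian clock, interneuron, endothelial and mural, CA1 pyramidal and thalamus markers and monoamine and neuromodulator receptors. With an estimated correlation 0 of the 39 lists passed by camera (0 at an unadjusted p under 0.05). By fry, which asks whether a set moves one way on balance, 0 lists passed and 8 had an unadjusted p under 0.05, the smallest adjusted p being 0.0558 for GABA receptors and transport.

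Mutant lines can carry a stretch of the donor strain around the altered gene, so genes near Ube3a were compared with the rest. Within 20 Mb of Ube3a, 13 of 299 genes differed at an unadjusted p under 0.01, against 874 of 19489 located elsewhere, an odds ratio of 0.97 (two-sided Fisher's exact test, p = 1). The odds ratio was 1.58 within 10 Mb and 1.27 within 40 Mb, with p = 0.289 and p = 0.157 in the same exact test, and 1.34 within 20 Mb without WT replicate 3 (p = 0.248). The called features 1500012K07Rik and Hddc3 lie 15.9 and 20.9 Mb from Ube3a on the same chromosome.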

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

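The tests of sex, microglia and genotype for the interferon list, both tests for the choroid plexus list and the 3 tests for chromosome 7 were chosen after the results were seen, as were the covariate and females-only alternatives. Of 236 groups of 4 values examined, 10 (4.24%) had 1 array far from the other 3, a gap above the 95% critical value of Dixon's test; chance gives about 1 in 20, so the number of such groups is no more than chance gives.

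The interferon list score of AS replicate 1, -0.31, lay apart from the 0.38 to 0.51 of the other AS arrays (gap over range 0.852), and Trim30a on the same array was -4.61 against -4.04 to -3.94 (0.849). The upper quartile of the microglia markers, 0.203, lay under the lower quartile of the interferon list, 0.256, which argues against a higher share of microglia as the whole cause, though the microglia scores of the 4 AS arrays all lay above the 4 WT scores and a change within microglia was not tested; 2 of the 32 list genes are shared with another list. With sex as a covariate the list's median log2 difference was 0.36 (camera adjusted p = 1.24e-07, range over alternatives with the preset correlation 1.75e-24 to 0.0409, but 0.746 with an estimated correlation and no covariate), while the difference in the list score was 0.44 with a 95% interval from -0.057 to 0.94, so sex cannot be excluded. A response in every AS animal may underlie the difference, yet the exact permutation p of the scores was 0.114 and 1 AS array lay among the WT arrays, so it cannot be told apart from a difference among individual animals. Each slide holds both groups equally, so a slide block cannot move the median and its adjusted p of 1.36e-08 decides nothing, while within the slides the scores differed by 0.30 and 0.71.

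The choroid plexus markers differed widely between animals of 1 group. Ttr, an abundant choroid plexus transcript named after its values were seen, was at 7.36, 6.20, 6.73 and 1.16 on WT replicates 1 to 4 and at 5.37, 1.47, 5.57 and 4.62 on AS replicates 1 to 4. Of the other 25 list members, 22 had the same lowest WT and lowest AS array as Ttr, as different amounts of choroid plexus in the dissected tissue would give, and 0 of the list's 26 genes are in another list. A lower level in AS animals stays open as well: the exact permutation p of the list scores was 0.229, and 4 against 4 arrays cannot tell it apart from uneven dissection.

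Among the features past adjusted p 0.05, 2 of 3 lie on chromosome 7, which holds 8.06% of the genes with a position, as do 7 of the 29 at adjusted p 0.10 (Fisher's exact test p = 0.007), while 4.14% of all chromosome 7 genes had an unadjusted p under 0.01 against 4.48% of the genes with a position. The hypergeometric probability of 2 or more of 3 was 0.0184, but the pattern was noticed in these 3 features, which are among the 29, and chance placement stays open for that reason. A stretch of donor-strain chromosome is a candidate explanation: within 2 Mb of both features, leaving them out, 5 of 83 genes had an unadjusted p under 0.01, an odds ratio of 1.37 (95% interval 0.432 to 3.35, Fisher's exact test p = 0.423), which leaves it open. Exchanging WT replicate 3 and AS replicate 1 gave 0 genes past adjusted p 0.05 by limma against 3 under the labels. At an unadjusted p under 0.05 it gave 1816 against 2787 under the labels, the most of any division. The labelled division is also the division by array position, which could by itself raise its counts, so they cannot decide on a swap. The 22 of 299 genes near Ube3a by which this exchange was noticed stay unexplained.

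Herc2 in AS replicate 1 was 1.31 against 1.17 in the other AS arrays (0.945). Ipw in WT replicate 4 was -1.12 against -2.20 to -2.05 (0.86). Scly in WT replicate 2 was -0.10 against -0.30 to -0.28 (0.867), and Adra1b in WT replicate 3 was 1.71 against 1.59 to 1.61 (0.832). The score of the UBE3A substrates in WT replicate 1 was -0.04 (0.953), that of the heat shock list was 0.45 against -0.093 to -0.004 (0.837), and that of immature neuron markers was 0.14 against -0.13 to -0.08 (0.832). The score of the sex-linked transcripts was -4.52 in WT replicate 3, the male of that group (0.922).

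The effect of genotype was tested for a difference between slides and between sexes. By limma, 0 genes passed for slide (1014 at an unadjusted p under 0.05) and 3 for sex (634), where the WT group holds 1 male; 0 of the 72 named entries passed in either.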

How the results depend on the processing

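The covariate and females-only alternatives were chosen after the data were seen. Scan followed slide, so it gave no separate fit. Of the results that answer a comparison, 149 values under alternatives were the same, 22 moved and 7 reversed. Here a count was the same if it stayed within 1.5-fold of the main count, so a fall from 2787 to 1956 genes was the same. Other values were the same if direction and threshold held. By direction and threshold, 1878 values of single genes and lists were the same, 43 newly passed, 43 no longer passed and 13 reversed. Probes near background are limited by their signal over it. The cause was not tested for any change below. The females-only and leave-one-out fits also rest on fewer arrays.

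The 3 features past adjusted p 0.05 became 10 with normexp and the 75th percentile, 13 with normexp and quantile normalization, 7 with the deposited log2 table, 31 with a trended and robust variance, 1 with the choroid plexus score as a covariate, 0 in females (limma; 1658 at an unadjusted p under 0.05) and 29 at adjusted p 0.10; leaving out single arrays gave 1 (WT replicate 2) to 15 (AS replicate 1). Hddc3 passed in 22 of 25 alternatives, 1500012K07Rik in 19 and ENSMUST00000101255 in 12. Unadjusted counts without 1 array were 1956 to 2887. The Ube3a difference ran from -0.24 to -0.09.

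The 7 lists past the threshold became 18 with normexp and the 75th percentile, 15 with the choroid plexus covariate (its own list left out), 0 with an estimated correlation, 0 by fry, and 5 to 13 without 1 array. The 4 marker lists became 0, 0 and 2 to 7. The region list had 1 probe past the threshold with every probe by itself. The odds ratio near Ube3a was 1.41 with the mean of probes, 1.17 with every probe, 1.503 in females, 1.58 within 10 Mb, 1.27 within 40 Mb, and 0.652 to 1.34 without 1 array.

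Nipa1 reversed to -0.0059 with quantile normalization, -0.0052 with normexp and quantile normalization, -0.0053 with the deposited log2 table, -0.0026 with sex as a covariate and -0.022 in females, and ran from -0.045 to 0.049 without 1 array. Ipw was -0.046 with the choroid plexus covariate and ran from -0.21 to 0.40, Atp10a from -0.0018 to 0.24, Magel2 from -0.033 to 0.41 and the dim Ube3a probe from -0.57 to 0.14.

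Same-numbered arrays correlated at 0.225, 0.272, 0.195 and 0.0538 in their deviations across genes, which are not independent replicates. The submitters describe the animals as 4 pairs without saying what pairs them, and as 1 of the correlations lay under 0.1 the numbers were not taken to pair the animals, which leaves a true pairing possible. As a hint from the data, each AS array and WT replicates 1 to 3 correlated best with their own number, and WT replicate 4 did not. Same-numbered arrays also had adjacent positions on the same slide, so these correlations cannot tell paired animals from neighbouring arrays. With the replicate block 0 genes passed (limma; 3736 at an unadjusted p under 0.05), the called features had adjusted p 0.0812, and the odds ratio near Ube3a was 1.09; the camera calls numbered 7.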

Other observations

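The counts under other splits of the 8 arrays for genes past adjusted p 0.05 and at an unadjusted p under 0.05 were tests chosen after those results were seen; the splits for region genes, lists, marker lists and genes near Ube3a were set out before.

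Neuromodulator receptor genes moved in both directions. Adjusted over the list alone, the adrenergic receptor gene Adra1b was lower in AS at a log2 difference of -0.33, with another probe at 0.13, while the serotonin receptor gene Htr7 and the somatostatin receptor gene Sstr3 were higher at 0.38 and 0.27. Members of other lists past the same threshold were the cortical markers Lamp5 and Scube1 at -0.38 and -0.54, the CA1 marker Wfs1 at -0.49, the perineuronal net gene Hapln4 at -0.35, the precursor marker C1ql1 at 0.31 and the BMP antagonist gene Chrd at 0.74. By fry without regard to direction, 10 lists passed, with adjusted p 0.000585 for oligodendrocyte precursor markers, 0.00747 for monoamine and neuromodulator receptors and for blood cell markers, 0.00841 for axon initial segment and sodium pump, 0.0088 for microglia, 0.0103 for CA1 pyramidal and 0.0117 for astrocyte markers, 0.0372 for cell cycle genes, 0.0386 for proteasome subunits and 0.0453 for retinoic acid signalling. This test asks whether members of a list move at all and does not compare the list with other genes. Of all genes tested, 13.9% had an unadjusted p under 0.05 (limma), so passing does not set these lists apart from other genes.

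The list scores of the 4 AS arrays all lay above the 4 WT scores for microglia markers (difference 0.09), GABA receptors and transport (0.10), proteasome subunits (0.07) and blood cell markers (0.42). Each had an exact permutation p of 0.0286, the smallest that 4 against 4 can give, and an adjusted p of 0.286 over the lists, so none passed. The differences on the first and the other slide were 0.10 and 0.08 for microglia markers, 0.14 and 0.05 for GABA receptors, and 0.04 and 0.09 for proteasome subunits.

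The 8 arrays can be divided into 4 and 4 in 35 ways. The real division gave 3 features past adjusted p 0.05, against at most 1 in any other, and 2787 genes at an unadjusted p under 0.05 against at most 2145, and in both only 1 division, the real one, gave as many. If the 8 arrays are freely exchangeable, this is a share under 0.05, though 1 of 35 is the smallest these arrays allow. Divisions that keep the slides balanced, or stay within the 4 pairs the submitters describe, are too few for such a share. With the replicate block 0 genes passed (limma; 3736 at an unadjusted p under 0.05). Whether chance is excluded for these counts therefore stays open, and they do not tell genotype from array position. Chance could not be excluded for the 7 lists past the threshold, where 26 of the 35 divisions gave as many and the highest other gave 18, nor for the 4 marker lists, where 13 did and the highest other gave 7. For the 0 region genes past the threshold (limma; 0 at an unadjusted p under 0.05) and the p of 1 for genes near Ube3a, all 35 divisions give as many or a p as small whatever the arrays hold, so these counts say nothing about chance; the highest other gave 1 region gene.

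The smallest p near Ube3a under another division was 1.91e-08, or 6.68e-07 times the 35 divisions, in the one that sets WT replicate 3 and AS replicates 2, 3 and 4 against the other arrays. This is the exchange of WT replicate 3 and AS replicate 1 that was tested as a swap. There 22 of 299 genes within 20 Mb had an unadjusted p under 0.01 against 327 of 19489 elsewhere, an odds ratio of 4.65. Of these, 17 lay between 51615413 and 53771071 on chromosome 7 (mm9), a stretch of 2.16 Mb, 9 of them higher and 8 lower in the first set of arrays. This points to a structure among the arrays that does not follow the labels, and it was noticed among the divisions. For a swap, the limma counts were 0 genes past adjusted p 0.05 against 3, and 1816 at an unadjusted p under 0.05 against 2787. They cannot decide on a swap, since the labelled division is also the division by array position. No other explanation for the structure was tested.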
